A study of Drosophila melanogaster with 12 samples.

How the data were processed

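The series holds 12 libraries of 3'-end sequencing from S2R+ cells, prepared from 2 ug of total RNA per the labels' protocols. The 8 used here are untreated cells and cells transfected with wild-type Elav, Fne or Rbp9, 2 libraries per group. The 4 libraries of RRM mutant proteins are not analysed here. Groups and replicate numbers were read from the sample titles. The labels give no treatment for the untreated cells and do not state whether these were mock transfected. The deposited table gives CPM per gene for 13777 genes, computed by the authors from gene counts by a method not stated in the sources used here, and the genome build is dm6 per the submitters' processing notes. The aligner and counter are not given in the sources used here, nor whether counting used strand. Values were taken as 1 level per gene, so the ratio of distal to proximal poly(A) sites, the pooled test on it, uridine content and the distance between sites were not computed.

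The CPM worth of 1 read was recovered for each library from the spacing of its values, which made 100% of the values whole reads within 0.01 of a read. The recovered depth ran from 4694825 to 14391952 reads, so 1 read equals 0.0695 to 0.213 CPM and 3 reads equal 0.208 to 0.639 CPM. Gene identifiers were matched to the annotation for 13684 genes, and 93 had no match. Coordinates are those of the Ensembl annotation of the BDGP6 assembly. rRNA-named genes (11) stayed in the table.

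Genes with a mean of at least 1 CPM over the 8 libraries (9114) were tested on log2(CPM + 1) with limma 3.58.1 (trend and robust empirical Bayes) under R 4.3.3, in 1 fit of all 8 libraries with group as the only term and 4 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. A group-only fit with this threshold was written before the data were examined, for all 12 libraries and the summed poly(A) sites of each gene. It was applied here to 8 libraries and 1 level per gene. The replicate number as a further term for the contrasts with untreated cells was also written beforehand. Contrasts between proteins were planned only for the ratio of distal to proximal poly(A) sites. Their expression tests, with or without that term, were added afterwards. Whether the numbers pair the samples was checked on the deviations of same-numbered libraries from their group means, which correlated at 0.55 to 0.869 in all 6 pairs of groups. The pairing rests on these data, since the labels do not say what a replicate number shares. Values of the paired fit (3 residual degrees of freedom) are given beside each result whose call it changes, and its standard errors accompany the log2 changes. Log2 changes of named genes are relative to the median of all tested genes in that contrast, while adjusted p-values test the unshifted change. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads.

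The 18 gene lists were written beforehand and tested with camera (preset correlation 0.01, and with an estimated correlation), with adjustment over the lists in a contrast. They were also tested with fry, a test of the members' own unshifted change. Counts of list members that pass are given over all tested genes and adjusted over the list alone. They are to be read beside the genes higher in the paired fit over all 9114 tested. These numbered 822 in ElavWT, 1374 in FneWT and 1617 in Rbp9WT. The filter on low values used all 8 libraries, most of them transfected. A gene silent in untreated cells thus entered only if it was higher after transfection. The filter kept 18 of 36 immune-induced, 14 of 17 muscle and 9 of 15 fat body genes. The shares that rose and the camera results of little-expressed lists are therefore in part set by the filter. Shared changes were compared with the overlap of independent lists and with 100 simulations of unchanged groups set against shared simulated untreated libraries. All simulated libraries were drawn independently with the residual spread of the paired fit and without a replicate effect. Neighbour shares were tested with 100000 permutations within 5 strata of expression, for genes with an untreated mean under 5 CPM and neighbours of at least 10 CPM within 2 kb. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.

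The genes named in each contrast with untreated cells are the 5 with the largest rise and the 5 with the largest fall among those that passed and whose libraries do not overlap between the groups. In the contrasts between proteins they are the 5 with the largest absolute change. elav, fne and Rbp9 are always named. Up to 4 members per list were picked by absolute change, and those of them that did not pass are left out of the text. In ElavWT these included Rdl (unshifted log2 change 5.375 and 0.046 in replicates 1 and 2) and Hsp23 (-1.227 and 4.916). The members named are thus not always the largest of their list. The fit with group alone passed no gene, so the rule was applied to the paired fit. Genes named without a value as 1 of 5 or fewer that passed were chosen after their values were seen.

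The code was tested on simulated data for ElavWT against untreated cells, with 200 of 9114 genes changed. The simulated replicate effect was equal in all groups and the dispersion was fixed at 0.04. The replicate term was thus right by construction, and the rates need not hold for the measured libraries. Without the replicate term limma and edgeR recovered 0%. With it limma recovered 41% of 2-fold and 93% of 4-fold changes with 16 false calls, and edgeR 38% and 93% with 4. Alternatives covered pseudocount, filter, scaling, rRNA-named genes, tool, replicate term and the omission of each library.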

Results

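Transcript 3' ends were sequenced from S2R+ cells, an established Drosophila melanogaster line with hemocyte-like properties, after transfection with constructs for ELAV/Hu family proteins. Elav, Fne and Rbp9, the 3 fly members of this family, are RNA-binding proteins made mainly in neurons, where they act on splicing and on the choice of poly(A) site. The 8 libraries analysed here form 4 groups of 2: untreated cells and cells that received wild-type Elav (ElavWT), Fne (FneWT) or Rbp9 (Rbp9WT). The 4 libraries of proteins with mutated RNA recognition motifs are not analysed here. The values are 1 level per gene in CPM, so the use of alternative poly(A) sites within a gene was not measured. Replicates 1 and 2 held 14391952 and 6808926 reads in untreated cells, 7093593 and 4694825 in ElavWT, 8047518 and 5497197 in FneWT, and 8761568 and 5020094 in Rbp9WT. A single read was worth 0.0695 CPM in the deepest library and 0.213 CPM in the shallowest. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

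HnRNP-K, which encodes an RNA-binding protein, was the most abundant gene in every replicate 1 library and took between 4.04% and 6.84% of the reads. In every replicate 2 library an 18S rRNA pseudogene led, with between 6.23% and 9.56%. The 11 rRNA-named genes together took 2.91% to 5.91% of the reads in replicate 1 and 15.4% to 24.8% in replicate 2. The first principal component, with 66.5% of the variance, placed the proteins' replicate 1 libraries at 62.3 to 82.5 and their replicate 2 libraries at -51.7 to -28.8. Untreated replicate 1 stood apart on the second component (17.2% of the variance) at 71.9, against at most 11.1 in any other library. The transfected libraries contained more genes than the untreated one of the same replicate number. At a common depth of 4694825 reads the expected number of genes with a read was 9730 in untreated replicate 1 and 10874, 11198 and 11076 in ElavWT, FneWT and Rbp9WT replicate 1. The replicate 2 numbers were 9099, 9607, 9986 and 10072. Of 4331 protein-coding genes at or below 0.5 CPM in both untreated libraries, 18.9%, 21.4% and 19.2% reached 1 CPM in replicate 1 of ElavWT, FneWT and Rbp9WT, and 5.3%, 7.3% and 6.6% in replicate 2.

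**Figure D1:**
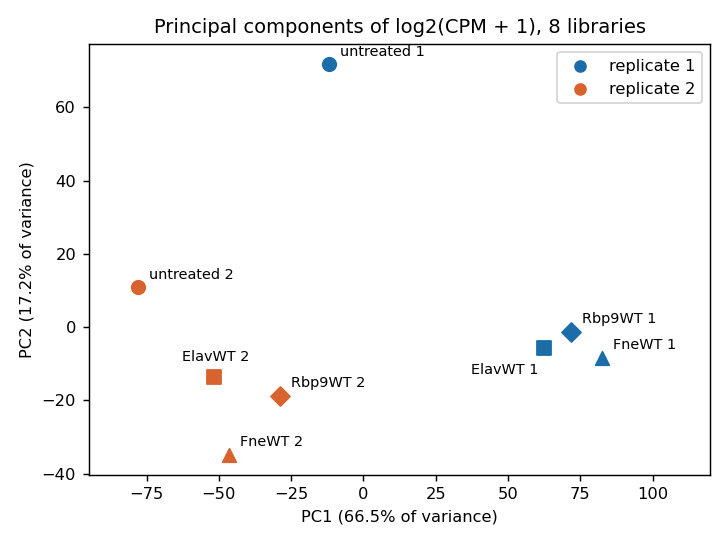
Scores of the 8 libraries on the first 2 principal components of log2(CPM + 1), with colour for the replicate number and shape for the group. Replicate 1 libraries of the 3 proteins lie between 62.3 and 82.5 on the first component, all replicate 2 libraries lie below 0, and untreated replicate 1 stands alone at 71.9 on the second.

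The genes of the expressed proteins were read first, as a check of the labels. Rbp9 (FBgn0010263, chromosome 2L, 2954762 to 2968434, plus strand) measured 713 and 58.8 CPM in Rbp9WT replicates 1 and 2 and at most 7.46 CPM elsewhere. Its log2 change against untreated cells, relative to the median gene, was 5.34 ± 0.66 (SE), with an adjusted p of 5.71e-04 from limma with the replicate number as a term. fne (FBgn0086675, chromosome X, 12917477 to 12950417, plus strand) measured 97.4 and 48.0 CPM in FneWT against 6.67 and 1.91 CPM in untreated cells, a log2 change of 3.60 ± 1.201 that did not pass (adjusted p = 0.136). It also measured 49.8 CPM in ElavWT replicate 1 and 114.8 CPM in Rbp9WT replicate 1, but 4.47 and 2.79 CPM in their replicate 2 libraries. elav (FBgn0260400, chromosome X, 509235 to 523226, minus strand) measured 29.2 and 26.6 CPM in the libraries labelled ElavWT against 24.9 and 37.3 CPM in untreated cells (log2 change -0.37 ± 0.30, adjusted p = 0.824). The highest elav levels were those of FneWT, at 42.7 and 59.7 CPM, without passing (adjusted p = 0.107). Its annotated span overlaps 1 other gene on each strand. Which 3' end the constructs carry is not given in the sources used here, so a level near that of untreated cells does not by itself speak against the label.

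**Figure D2:**
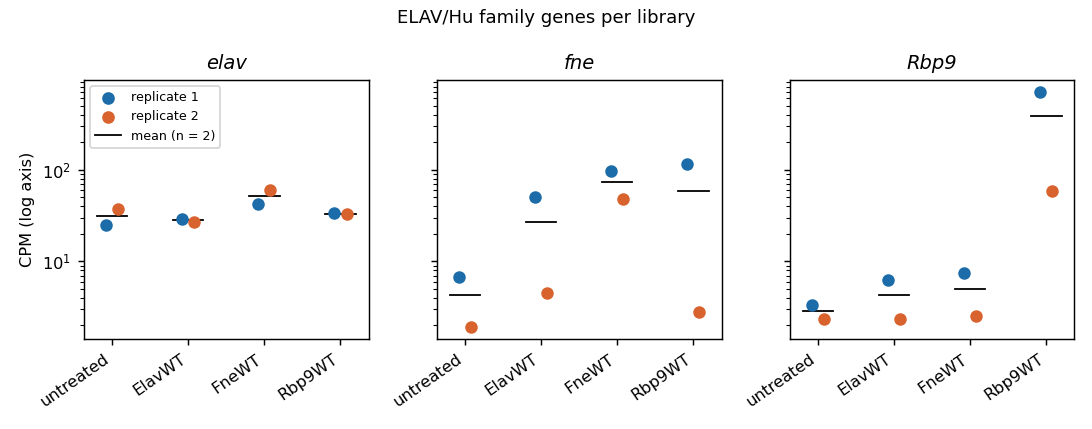
CPM of elav, fne and Rbp9 in each library on a log axis, with points for replicates 1 and 2 and a bar for the mean of 2 libraries. Rbp9 reaches 713 and 58.8 CPM in Rbp9WT, fne exceeds 40 CPM in both FneWT libraries and in replicate 1 of ElavWT and Rbp9WT, and elav lies between 24.9 and 59.7 CPM in all 8 libraries.

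The comparison with untreated cells asks which transcript levels differ after transfection of each construct into a cell type that is not neuronal. With the group as the only term, limma passed no gene of 9114 at an adjusted p under 0.05 in ElavWT, FneWT or Rbp9WT. At an unadjusted p under 0.05 there were 444, 677 and 666 genes. edgeR on the recovered reads also passed 0 in each, while DESeq2 passed 263, 436 and 266. Same-numbered libraries deviated together, and with the replicate number as a term limma passed 921 genes in ElavWT (822 higher, 99 lower), 1551 in FneWT (1374 higher, 177 lower) and 1684 in Rbp9WT (1617 higher, 67 lower). All of these moved the same way in both replicates, which follows largely from how the paired fit selects genes. Under CPM scaling the median gene itself lay 0.25, 0.28 and 0.42 log2 units above untreated cells. By replicate it lay 0.39, 0.51 and 0.52 above in replicate 1 and 0.08, 0.05 and 0.3 in replicate 2. Every log2 change given here is relative to the shift over both replicates. Its test is of the unshifted change. Rescaling by median ratios took these shifts to 0.04, 0.02 and 0.04 and changed the split of the paired calls from 89.3%, 88.6% and 96% higher to 73.7%, 65.6% and 68.6% higher (703 and 251, 1119 and 588, 944 and 433 genes). Without the filter on low values the paired fit passed 0 genes in each contrast, with 1876, 2375 and 2446 at an unadjusted p under 0.05. The gene names below come from the paired fit with the filter.

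**Figure D3:**
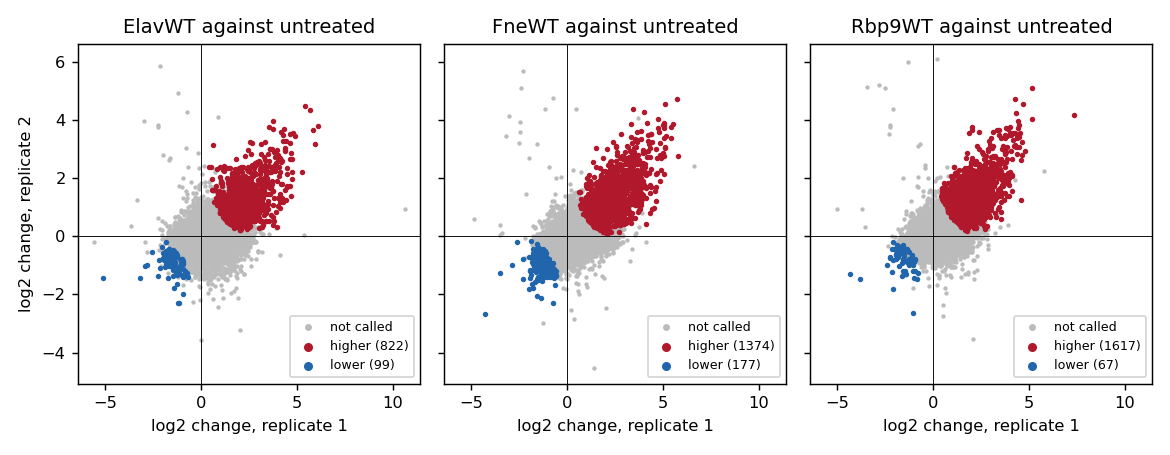
Log2 change of each of 9114 genes against the untreated library of the same number, as measured, replicate 1 across and replicate 2 up, 1 panel per protein. Red and blue points passed limma with the replicate number as a term (822 and 99, 1374 and 177, 1617 and 67 genes) and all lie in the quadrants where both replicates have 1 sign.

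In the libraries labelled ElavWT, genes that were nearly silent in untreated cells rose most. osk (FBgn0003015, chromosome 3R, 8935126 to 8938395), whose protein assembles germ plasm in the oocyte, measured 96.0 ± 74.9 CPM (SD, n = 2) against 1.53 ± 0.496 CPM. NLaz (FBgn0053126, chromosome 2L, 1359837 to 1361821), which encodes a secreted lipocalin, measured 34.7 ± 18.6 against 0.069 ± 0.098 CPM, and the chitinase-family gene Cht9 42.0 ± 41.1 against 0.035 ± 0.049 CPM. Their log2 changes were 4.78 ± 0.35, 4.71 ± 0.42 and 4.69 ± 0.47 (SE; adjusted p = 1.31e-09, 2.44e-08 and 5.04e-07), followed by CG6044 at 4.50 ± 0.49 and CG14490 at 4.30 ± 0.60. CG34330 (FBgn0085359, chromosome X, 19068275 to 19068973) fell from 44.1 ± 40.2 to 3.12 ± 2.82 CPM and Sirup (FBgn0031971, chromosome 2L, 7998869 to 7999676), an assembly factor of succinate dehydrogenase, from 705 ± 745 to 100.05 ± 48.7 CPM. Their log2 changes were -3.53 ± 0.75 and -2.56 ± 0.51 (adjusted p = 0.0251 and 0.0203). The untreated libraries differed widely from each other in both. The diphthamide synthesis gene Dph1 (-2.24 ± 0.42), CG10512 (-2.16 ± 0.41) and the extracellular matrix gene fat-spondin (-2.06 ± 0.30) fell too. osk, Cht9, CG6044, CG14490, Sirup, CG10512 and fat-spondin overlap other annotated genes, from which their reads may not be separable because the strand used in counting is not given in the sources used here. The count of 921 fell to 294 without untreated replicate 1 and 329 without ElavWT replicate 1, and rose to 2796 without untreated replicate 2.

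Among the gene lists, 9 of 31 neuron markers rose in the libraries labelled ElavWT and none fell (11 adjusted over the list alone). They included Nrg, the L1-type adhesion molecule of axons (101 ± 78.5 against 13.4 ± 8.97 CPM, log2 change 2.49 ± 0.28), the presynaptic adhesion gene Nrx-1 (1.85 ± 0.37) and the acetylcholine receptor subunit nAChRalpha5 (1.73 ± 0.39). The list lay above other genes by camera (adjusted p = 8.12e-05), a call lost at adjusted p = 0.754 with an estimated correlation. Of 42 genes with extended neural 3' UTRs or known as ELAV targets, 9 rose, with Nrg, the DAZ-family gene bol (1.53 ± 0.30) and the homeotic gene Antp (1.44 ± 0.49) in front, and 1, stai, fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00254, and 0.754 with an estimated correlation). Single markers of other cell types rose beside them: 5 of 14 muscle genes, led by tropomyosin 2 (Tm2, 3.07 ± 0.53) and myosin light chain 2 (Mlc2, 1.67 ± 0.49), the epithelial polarity genes crb (1.502 ± 0.50) and sdt (1.06 ± 0.30) of 9 glia and epithelial markers, osk and spn-E (1.00 ± 0.35) of 10 germline markers, and Apoltp (1.19 ± 0.39) of 9 fat body markers. Adjusted over the list alone, 5, 2, 2 and 3 genes of these 4 lists passed. Nrg, Nrx-1, nAChRalpha5, Antp and spn-E overlap other annotated genes. The muscle list passed camera with the replicate term only (adjusted p = 0.0474, 0.31 without it, and 0.754 with an estimated correlation), and the fat body list without it only (0.0148, against 0.0676 with it, and adjusted p = 0.79 with an estimated correlation). With the replicate term and median-ratio scaling the fat body list passed too (0.0381). The glia and epithelial and the germline lists did not pass camera (adjusted p = 0.298 and 0.24).

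In the libraries labelled ElavWT single stress, immune and signalling genes rose. Only 18 of 36 immune-induced genes passed the filter on low values, to which the transfected libraries contributed. Over all genes tested 822 of 9114 rose, a share close to that of the signalling (4 of 39) and neural transcription factor (2 of 21) genes. Of 26 heat shock and stress genes 5 rose, among them the co-chaperone gene stv (2.47 ± 0.42), the small heat shock gene Hsp67Bc (1.68 ± 0.43) and Gadd45 (1.67 ± 0.36), but the list as a whole did not pass camera (adjusted p = 0.192). Of 18 immune-induced genes 4 rose, including the antibacterial peptide genes DptA (2.29 ± 0.53) and DptB (1.55 ± 0.50) and the receptor gene PGRP-LF (1.78 ± 0.46), and vir-1 fell (camera adjusted p = 0.0478, 0.178 without the replicate term, and 0.754 with an estimated correlation). The JAK/STAT ligand genes upd3 (2.45 ± 0.34) and upd2 (1.74 ± 0.41), Egfr (1.68 ± 0.38) and put were the 4 of 39 signalling genes that rose. grh (1.17 ± 0.36) and ham (1.08 ± 0.39) rose among 21 transcription factors with neural roles. PPO2 (1.88 ± 0.44) rose and Pxn (-1.25 ± 0.32) fell among 18 hemocyte genes. Sxl (1.16 ± 0.32) rose and the SR protein gene x16 (-1.44 ± 0.29) fell among 35 splicing and hnRNP genes. Adjusted over the list alone, 5 stress, 6 immune, 5 signalling, 3 neural transcription factor, 2 hemocyte and 1 splicing gene rose, and 1 gene each of the immune, neural transcription factor, hemocyte and splicing lists fell. The hemocyte list lay slightly above other genes by its median (0.12) and below them by camera (adjusted p = 0.857). The signalling, neural transcription factor and splicing lists did not pass camera either (adjusted p = 0.24, 0.094 and 0.327). DptB, PGRP-LF, Egfr, grh, ham, Pxn, Sxl and x16 overlap other annotated genes.

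In ElavWT 2 cell cycle genes and 1 ribosomal protein gene fell, the latter not when adjusted over the list alone. The mitotic kinase gene aurA (-1.47 ± 0.32) and the Cdc20 homologue fzy (-1.42 ± 0.31) were the 2 of 26 cell cycle genes that fell, and the list's median was -0.76 relative to all genes (camera adjusted p = 6.12e-07, and 0.164 with an estimated correlation). Of 83 cytosolic ribosomal protein genes only RpL37A (-1.37 ± 0.36) fell, with a list median of -0.78 (camera adjusted p = 1.85e-14, and 0.754 with an estimated correlation). None of 26 oxidative phosphorylation genes passed, although the list lay lower (median -0.54, camera adjusted p = 7.12e-05, and 0.754 with an estimated correlation). None of 19 translation factors and none of 17 cleavage and polyadenylation factors passed (camera adjusted p = 0.0687 and 0.298, the first 0.0322 without the replicate term and 0.79 with an estimated correlation). The 26 names written for the polyadenylation list gave 17 measured genes, so the list may be incomplete. The median change of the polyadenylation factors was 0.04 as measured, while camera placed them below other genes. The ELAV/Hu family as a list of 3 did not pass camera in ElavWT, FneWT or Rbp9WT (adjusted p = 0.772, 0.107 and 0.0641).

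In FneWT the steepest rises were those of 2 neighbouring genes. CG18568 (FBgn0033888, chromosome 2R, 13971325 to 13972834) measured 52.9 ± 39.1 CPM (SD, n = 2) against 0.278 ± 0.393 CPM in untreated cells, and the sulfotransferase gene St4 (FBgn0033887, chromosome 2R, 13969910 to 13971263), on the same minus strand, 67.2 ± 44.3 against 1.23 ± 0.911 CPM. Their log2 changes were 4.93 ± 0.35 and 4.54 ± 0.34 (SE; adjusted p = 6.99e-10 and 7.32e-10). The lipid kinase gene PIP5K59B (4.42 ± 0.43), osk (4.30 ± 0.35, from 1.53 ± 0.496 to 74.7 ± 65.2 CPM) and the matrix metalloproteinase gene Mmp1 (4.19 ± 0.33, from 6.68 ± 5.09 to 216 ± 221 CPM) followed. CG34330 (-3.76 ± 0.75, adjusted p = 0.013) and Sirup (-2.68 ± 0.51, adjusted p = 0.0116) fell most, then CG15861 (-2.22 ± 0.38), fat-spondin (-2.18 ± 0.30) and pll (-2.17 ± 0.38), the kinase gene of the Toll pathway. PIP5K59B, osk, Mmp1, Sirup, CG15861, fat-spondin and pll overlap other annotated genes. The count of 1551 became 508 without untreated replicate 1, 3465 without untreated replicate 2, 278 without FneWT replicate 1 and 932 without FneWT replicate 2.

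Of the 42 genes with neural 3' UTR extensions or known as ELAV targets, 19 rose in FneWT and none fell (25 adjusted over the list alone). The list holds fne, the gene of the transfected protein, which did not pass over all genes but enters camera. It shares elav, Nrg, Syt1 and para with the neuron markers. Nrg (2.82 ± 0.28), bol (2.14 ± 0.30) and the TRIM-NHL gene mei-P26 (2.13 ± 0.31, from 96.8 ± 6.01 to 529 ± 157 CPM) led (camera adjusted p = 7.63e-07, and 0.496 with an estimated correlation). Neuron markers rose in 14 of 31 cases (16 adjusted over the list alone, beside 1 that fell), with Nrg, Nrx-1 (2.57 ± 0.37), the active zone gene Rim (2.44 ± 0.36) and the SNARE gene Snap25 (1.87 ± 0.29) in front (camera adjusted p = 3.78e-05, and 0.496 with an estimated correlation). The neural transcription factors onecut (1.86 ± 0.53), ham (1.68 ± 0.39), cas (1.67 ± 0.54) and scrt (1.49 ± 0.58) were among 9 of 21 that rose (15 adjusted over the list alone; camera adjusted p = 7.03e-04, and 0.496 with an estimated correlation). Markers of other cell types rose as well, with 7, 5, 5 and 3 genes of the next 4 lists passing when adjusted over the list alone. They were 7 of 14 muscle genes, with Tm2 (3.12 ± 0.53), Mlc2 (2.46 ± 0.49) and Mef2 (1.95 ± 0.45), 4 of 9 fat body genes, with Adh (1.62 ± 0.44) and Yp3 (1.46 ± 0.50), 4 of 9 glia and epithelial genes, with crb (1.92 ± 0.50), and osk and tud (0.83 ± 0.33) of 10 germline genes. The muscle and fat body lists passed camera (adjusted p = 0.00167 and 0.0151, and 0.496 for both with an estimated correlation), while the glia and epithelial and the germline lists did not (adjusted p = 0.061 and 0.15).

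Among stress and immune genes in FneWT, Hsp67Bc (3.00 ± 0.43) and stv (2.88 ± 0.42) were among 5 of 26 stress genes that rose, Hsp60A fell, and DptB (2.30 ± 0.50), AttD (1.99 ± 0.65) and DptA (1.82 ± 0.53) were among 5 of 18 immune-induced genes that rose. Neither list passed camera (adjusted p = 0.145 and 0.061), but the immune list did with median-ratio scaling (0.038, and adjusted p = 0.496 with an estimated correlation). Adjusted over the list alone, 5 stress, 7 immune, 5 hemocyte, 8 signalling and 1 splicing gene rose, and 1 stress and 1 signalling gene fell. The collagen IV genes Col4a1 (1.24 ± 0.34) and vkg (1.18 ± 0.35), Ppn (2.06 ± 0.60) and drpr rose among 18 hemocyte genes (camera adjusted p = 0.117). The ligand genes upd3 (2.54 ± 0.34) and Ser (1.41 ± 0.44) and Egfr (1.32 ± 0.38) were among 8 of 39 signalling genes that rose (camera adjusted p = 0.0163, 0.0777 without the replicate term, and 0.539 with an estimated correlation). Sxl (1.72 ± 0.32), how (0.64 ± 0.32) and Rbfox1 rose among 35 splicing and hnRNP genes (camera adjusted p = 0.386). Over all genes tested 1374 of 9114 rose, a larger share than these 3 of 35. The stress (5 of 26) and signalling (8 of 39) counts lay not far above that share. In the opposite direction, 6 of 26 cell cycle genes fell, including Mcm5 (-1.47 ± 0.34), aurB (-1.31 ± 0.30), aurA (-1.21 ± 0.32) and fzy (-1.21 ± 0.31), with camera adjusted p = 3.4e-06 and 0.209 with an estimated correlation. RpS29 (-1.64 ± 0.37) and RpL36 (-1.58 ± 0.38) were among 8 of 83 ribosomal protein genes that fell, while RpS28-like rose from 0 in both untreated libraries to 2.26 ± 1.44 CPM (list median -1.04, camera adjusted p = 6.96e-20, and 0.496 with an estimated correlation). The oxidative phosphorylation list lay lower with none of 26 genes passing (median -0.63, camera adjusted p = 3.4e-06, and 0.496 with an estimated correlation). The 19 translation factors lay lower (camera adjusted p = 0.0151, and 0.496 with an estimated correlation), although the genes that passed, eEF1alpha2 (1.56 ± 0.53) and eIF5 (0.70 ± 0.32), both rose. None of 17 cleavage and polyadenylation factors passed (camera adjusted p = 0.061, 0.0304 with median-ratio scaling, and 0.496 with an estimated correlation), and their median was 0.1 as measured, where their mean was -0.06. DptB, drpr, Egfr, Sxl, aurA, fzy, RpS29, RpS28-like and eIF5 overlap other annotated genes, as do Nrg, Nrx-1, Rim, Snap25, ham and Adh above.

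In Rbp9WT, Rbp9 itself rose most, and CG18568 (4.71 ± 0.35, SE) and St4 (4.08 ± 0.34) again stood high, at 43.6 ± 14.3 and 47.8 ± 10.2 CPM (SD, n = 2). The sodium pump subunit gene nrv3 (FBgn0032946, chromosome 2L, 21380000 to 21393319) measured 143 ± 74.3 against 4.77 ± 2.59 CPM, a log2 change of 4.21 ± 0.29 (adjusted p = 1.07e-10), and CG2278 136 ± 95.97 against 3.94 ± 1.01 CPM (4.19 ± 0.37, adjusted p = 8.46e-08). CG34330 (-3.24 ± 0.75, adjusted p = 0.0307) and Sirup (-3.04 ± 0.51, adjusted p = 0.00672) fell most, followed by CG16888 (-2.37 ± 0.52), the rRNA precursor gene pre-rRNA:CR45856 (34.3 ± 10.7 against 163 ± 150 CPM, adjusted p = 4.19e-04) and CG10512 (-2.11 ± 0.41). Rbp9, CG2278, Sirup, CG16888, CG10512 and the rRNA precursor gene, which has near-identical copies, overlap other annotated genes. The count of 1684 became 563 without untreated replicate 1, 3429 without untreated replicate 2, and 622 and 623 without Rbp9WT replicates 1 and 2.

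Of the 42 genes with neural 3' UTR extensions or known as ELAV targets, 16 rose in Rbp9WT and none fell (21 adjusted over the list alone), led by bol (2.15 ± 0.30), Nrg (2.04 ± 0.28) and mei-P26 (1.81 ± 0.31), with camera adjusted p = 6.71e-04 and 0.637 with an estimated correlation. Neuron markers rose in 11 of 31 cases (16 adjusted over the list alone), with Nrx-1 (2.85 ± 0.37) and Snap25 (1.52 ± 0.29) beside Nrg (camera adjusted p = 4.85e-04, 0.0949 without the replicate term, and 0.637 with an estimated correlation). Of the other cell types, Tm2 (2.69 ± 0.53), Mef2 (2.40 ± 0.45), Mlc2 (1.44 ± 0.49) and sls (1.12 ± 0.33) rose among 14 muscle genes. Adh (2.62 ± 0.44) and Apoltp (1.72 ± 0.39) were among 4 of 9 fat body genes that rose. So were crb (1.63 ± 0.50) and sdt (1.32 ± 0.30) among 4 of 9 glia and epithelial genes, and osk (3.502 ± 0.35) and spn-E (1.06 ± 0.35) among 10 germline genes. Adjusted over the list alone, 4, 5, 5 and 6 genes of these 4 lists rose. None of the 4 passed camera (adjusted p = 0.116, 0.083, 0.116 and 0.0907), although the fat body list did without the replicate term (0.0162, and adjusted p = 0.531 with an estimated correlation). With the replicate term and median-ratio scaling the muscle and fat body lists passed (0.0426 and 0.0374, and adjusted p = 0.637 for both with an estimated correlation). The signalling list had 15 of 39 genes that rose (20 adjusted over the list alone), among them upd3 (2.53 ± 0.34), the activin receptor gene put (1.39 ± 0.29) and hh (1.39 ± 0.58), with camera adjusted p = 0.015, 0.0949 without the replicate term, and 0.637 with an estimated correlation.

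Hsp67Bc (2.94 ± 0.43) and stv (2.48 ± 0.42) were among 6 of 26 stress genes that rose in Rbp9WT. So were DptB (1.95 ± 0.50) and PGRP-LF (1.63 ± 0.46) among 5 of 18 immune-induced genes and Ppn (1.59 ± 0.60) and vkg (1.22 ± 0.35) among 5 of 18 hemocyte genes. The same held for onecut (1.72 ± 0.53) and grh (1.32 ± 0.36) among 7 of 21 neural transcription factors and for Sxl (1.18 ± 0.32), U2af50 (0.88 ± 0.30) and qkr58E-3 (0.69 ± 0.30) among 4 of 35 splicing and hnRNP genes. None of these 5 lists passed camera, with adjusted p = 0.295, 0.116, 0.217, 0.0503 and 0.241. With median-ratio scaling the neural transcription factor list did (0.0233, and adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 7, 5, 7, 9 and 4 of their genes rose. Over all genes tested 1617 of 9114 rose, a larger share than 4 of 35 splicing genes and not far below 6 of 26 stress genes. RpL37A (-1.70 ± 0.36) and RpS30 (-1.61 ± 0.35) were among 11 of 83 ribosomal protein genes that fell (list median -1.22, camera adjusted p = 5.33e-32, and 0.637 with an estimated correlation). Adjusted over the list alone, no ribosomal protein gene passed in ElavWT, FneWT or Rbp9WT. aurB (-1.58 ± 0.30) was the single cell cycle gene of 26 that fell (camera adjusted p = 1.01e-04, and 0.308 with an estimated correlation). That count tests the unshifted change, and over all genes lower calls went from 67 to 433 with median-ratio scaling. eIF5 (1.03 ± 0.32) was the single translation factor of 19 that rose while the list lay lower (camera adjusted p = 0.00209, and 0.637 with an estimated correlation). No oxidative phosphorylation or cleavage and polyadenylation gene passed (camera adjusted p = 1.01e-04 and 0.0939, the second 0.0291 with median-ratio scaling, and both 0.637 with an estimated correlation). DptB, PGRP-LF, grh, Sxl, qkr58E-3, RpL37A and eIF5 overlap other annotated genes, as do Nrg, Nrx-1, Snap25, sls, Adh and spn-E above.

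**Figure D4:**
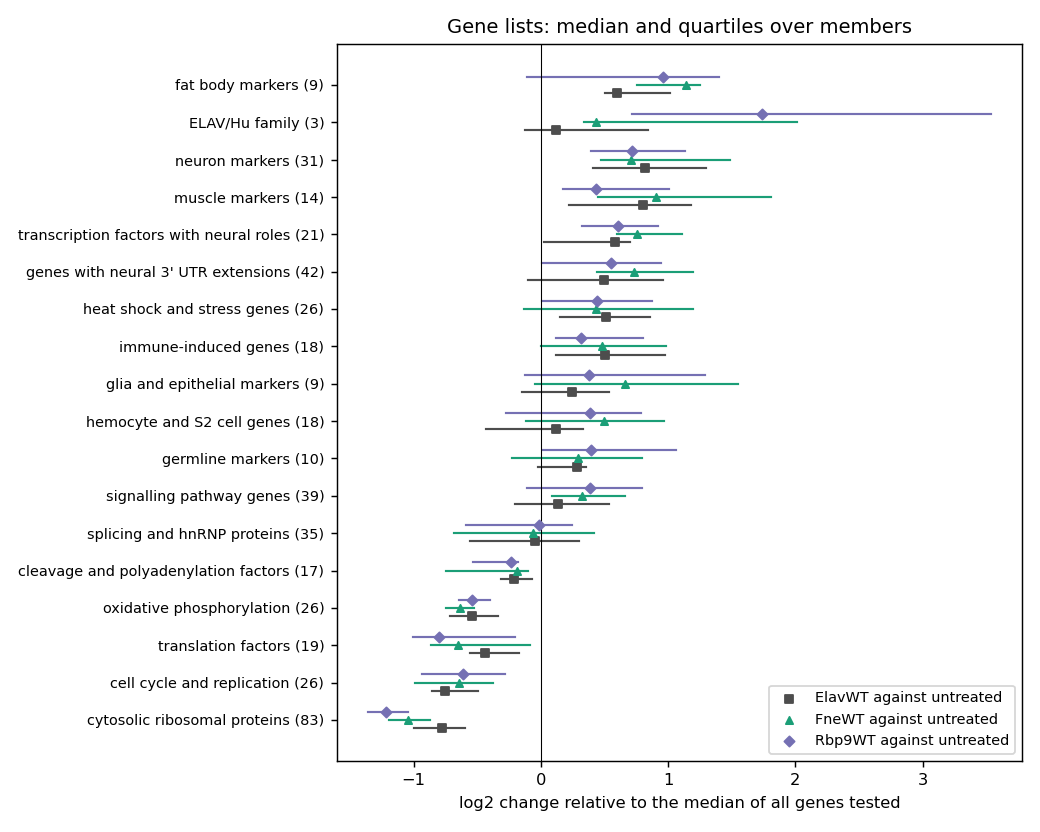
Median (symbol) and quartiles (line) of the log2 change of each gene list's members against untreated cells, relative to the median of all genes tested, with the number of members tested in brackets. The medians of neuron, muscle and fat body markers lie right of 0 in each protein, and ribosomal protein genes lie furthest left, with medians of -0.78, -1.04 and -1.22 in ElavWT, FneWT and Rbp9WT.

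Many of the same genes moved in the libraries of all 3 proteins, although elav itself was not raised in those labelled ElavWT. osk, CG18568, St4, nrv3, Nrg, bol and mei-P26 were among 579 genes higher in ElavWT, FneWT and Rbp9WT alike in the paired fit, and CG34330, Sirup and fat-spondin were among 22 genes lower in each. Independent lists of these sizes would share 22 and 0 genes. ElavWT and FneWT shared 637 higher genes (123.9 for independent lists), ElavWT and Rbp9WT 648 (145.8), and FneWT and Rbp9WT 1056 (243.8). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.837, 0.808 and 0.886 for these pairs. In 100 simulations of unchanged groups that shared simulated untreated libraries, r was 0.499. The covariances were 0.546, 0.475 and 0.595 against a simulated 0.084, and at most 3 genes passed in all 3 simulated contrasts. With the change of 1 protein taken from replicate 1 and that of another from replicate 2, so that no library was shared, r was 0.408 to 0.622. The simulations held no replicate effect and no trait particular to the measured untreated libraries, so they may understate what shared controls give. The 2 untreated libraries cannot be split further, so part of the excess may come from the shared controls. The 579 genes became 164 without untreated replicate 1 and 1968 without untreated replicate 2, and the 22 genes became 4 and 252. With median-ratio scaling 454 genes were higher and 112 lower with all 3 proteins, and with edgeR 729 and 254.

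Direct comparisons between the protein groups asked where they differ. elav was not raised in the libraries labelled ElavWT, so a difference is between labelled groups. FneWT exceeded ElavWT for CG14984 (55.8 ± 48.3 against 5.33 ± 3.62 CPM, log2 change 2.93 ± 0.44, adjusted p = 0.00412), CG6785 (2.88 ± 0.46), SmydA-5 (2.85 ± 0.57), CG13694 (2.66 ± 0.47) and asRNA:CR45600 (2.55 ± 0.44), the 5 with the largest change among 16 genes that passed the paired fit (15 higher, 1 lower). Rbp9WT exceeded ElavWT for Rbp9 (5.25 ± 0.66, adjusted p = 0.0155), swi2 (2.66 ± 0.52), CG30398 (2.54 ± 0.47) and SmydA-5 (2.49 ± 0.57) among 54 genes (51 higher, 3 lower). mthl15, a gene of the Methuselah-like receptor family, also passed (adjusted p = 0.0173), at 7.73 ± 6.99 CPM in Rbp9WT and 0 in both ElavWT libraries, where 3 reads amount to 0.423 and 0.639 CPM. No gene passed between Rbp9WT and FneWT in the paired limma fit, where 506 had an unadjusted p under 0.05. edgeR with the same term passed 1 and DESeq2 4. Rbp9 itself did not pass that limma fit, at 713 and 58.8 CPM in Rbp9WT against 7.46 and 2.55 CPM in FneWT. The lack of calls therefore does not show that these groups are alike. Without the replicate term limma passed 0 genes in each of the 3 contrasts (62, 88 and 25 at an unadjusted p under 0.05). CG6785, CG13694, asRNA:CR45600, swi2, CG30398 and Rbp9 overlap other annotated genes. With the replicate term but no filter on low values, limma passed no gene in either contrast with ElavWT (939 and 1197 at an unadjusted p under 0.05). Between Rbp9WT and ElavWT the paired fit passed 32 higher and 7 lower genes with median-ratio scaling, 35 and 19 with edgeR, and 52 and 28 with DESeq2. Without FneWT replicate 1 or 2 the 16 genes became 1 or 0, without ElavWT replicate 1 they became 46, and the 54 genes became 31 and 34 without ElavWT replicates 1 and 2, and 4 and 8 without Rbp9WT replicates 1 and 2.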

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

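No test of a technical cause was made for the differences in this part. They were picked out because 2 protein groups, each compared with the same untreated cells, differed by a direct test. Between FneWT and ElavWT 16 genes passed with the replicate number as a term, 15 of them higher in FneWT. The single gene lower in FneWT was NLaz, the lipocalin gene with 1 of the largest rises in the libraries labelled ElavWT, at 7.62 ± 4.86 against 34.7 ± 18.6 CPM (SD, n = 2; log2 change -2.11 ± 0.42, adjusted p = 0.0341). Between Rbp9WT and ElavWT 54 genes passed, of which 51 were higher in Rbp9WT (32 of 39 with median-ratio scaling). The 3 that were lower were CG1648 (2.61 ± 2.28 against 21.4 ± 17.3 CPM, adjusted p = 0.0146), CG6044 (5.62 ± 2.87 against 35.5 ± 33.7 CPM, adjusted p = 0.0386) and Gr5a, a gustatory receptor gene (6.82 ± 5.70 against 32.3 ± 24.3 CPM, adjusted p = 0.0296). These 4 genes were singled out after their values were seen. With the replicate term but no filter on low values no gene passed in either contrast. Without that term and without the filter 0 and 4 genes passed.

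Whether the proteins differ because of binding to different RNAs or because of unequal protein levels was not tested, and the transfected proteins were not measured in these libraries.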

How the results depend on the processing

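The replicate block against untreated cells, and without the block the smaller pseudocount, no filter, median-ratio scaling, an adjusted p under 0.1, the estimated correlation and the omission of each library, were written beforehand. All other alternatives, including every change made on top of the block and all for the contrasts between proteins, were chosen after seeing the data. The numbers were taken to pair the samples because deviations of same-numbered libraries correlated in these data. The correlations were 0.55 to 0.678 with untreated cells and 0.767 to 0.869 between proteins. Values with the replicate block are therefore given beside those without it. With group alone limma passed 0 genes in every contrast. In the order ElavWT, FneWT and Rbp9WT against untreated cells, the counts were 921, 1551 and 1684 with the replicate block, 1044, 1662 and 1820 with a pseudocount of 0.5 CPM added to it, 954, 1707 and 1377 with median-ratio scaling, and 893, 1621 and 1612 with rRNA-named genes removed. They were 1534, 2364 and 2046 with edgeR, 1351, 2077 and 1860 with DESeq2, 543, 1075 and 1895 with only the 4 libraries compared and 667, 1099 and 1337 at a mean of at least 5 CPM. With the block and each library left out in turn they ranged from 294 to 2796 in ElavWT (329 and 804 without its own replicates 1 and 2), 278 to 3465 in FneWT (508 without untreated replicate 1, 932 without FneWT replicate 2) and 563 to 3429 in Rbp9WT (622 and 623 without its own replicates 1 and 2). Without the block, DESeq2 passed 263, 436 and 266 genes, and no filter gave 0, 5 and 9. The block without a filter passed 0. The cause was not tested. A lone library left in a group was assumed to vary like the other groups.

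Between FneWT and ElavWT the block passed 16 genes, as it did with the smaller pseudocount (16), median-ratio scaling (16) and rRNA-named genes removed (16), against 21 with edgeR, 34 with DESeq2, 78 with 4 libraries, 5 at 5 CPM, 0 without a filter and 0 to 46 with a library left out. DESeq2 without the block passed 1. Between Rbp9WT and ElavWT the same settings gave 54, 54, 39, 31, 54, 80, 661, 19, 0 and 4 to 34 (8 without Rbp9WT replicate 2), and without the block DESeq2 passed 4 and no filter 4. Between Rbp9WT and FneWT the block passed 0, the smaller pseudocount 1, edgeR 1, DESeq2 4, 4 libraries 115, and 1 to 6 with a library left out, while without the block DESeq2 passed 1 and no filter 3. The cause was not tested.

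Of the gene lists, 7, 9 and 6 passed camera in ElavWT, FneWT and Rbp9WT without the block, and 0 in each with an estimated correlation, with the block or without. With the block and median-ratio scaling 11 passed in Rbp9WT. By fry with the block only the cell cycle list passed, in ElavWT and FneWT (fry adjusted p = 0.0326 and 0.0241), and no list passed in Rbp9WT. Genes higher with all 3 proteins numbered 0 without the block, 579 with it, 834 at an adjusted p under 0.1, 454 with median-ratio scaling, 729 with edgeR and 164 to 1968 with an untreated library left out. Genes lower with all 3 numbered 0, 22, 58, 112, 254 and 4 to 252. The cause was not tested.

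Signs reversed for the following unshifted log2 changes, and the cause was not tested. The change of elav, ElavWT vs untreated (-0.127) ran from -0.408 to 0.154 with a library left out, and from -0.358 to 0.105 with the block (0.102 without untreated replicate 2). That of Rbp9, ElavWT vs untreated ran from -0.189 to 0.918 (-0.439 to 1.169 with the block) and that of Rbp9, FneWT vs untreated from -0.104 to 1.15 (-0.281 to 1.327 with the block). For elav, Rbp9WT vs untreated (0.109) it was -0.304 with median-ratio scaling, -0.432 with edgeR and -0.367 with DESeq2, and with the block -0.304, -0.361 and -0.3. With a library left out it ran from -0.172 to 0.39, and with the block from -0.119 to 0.337 (-0.056 without Rbp9WT replicate 1). Without the block, the leave-one-out range was -0.318 to 4.616 for fne, Rbp9WT vs untreated, -0.279 to 3.116 for grh, ElavWT vs untreated and -0.226 to 2.886 for ham, ElavWT vs untreated. It was -0.021 to 3.285 for PGRP-LB, FneWT vs untreated, -0.312 to 2.28 for eIF5, FneWT vs untreated, -0.258 to 3.795 for scrt, FneWT vs untreated and -0.067 to 3.133 for sls, Rbp9WT vs untreated. In each of these 7 the lowest value came without replicate 1 of the protein.

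Of 174 gene results that passed with the block (139 higher, 35 lower), 165 still passed with median-ratio scaling, 159 with edgeR and 167 with DESeq2, 81 of 160 without untreated replicate 1 and 159 of 160 without untreated replicate 2. Without replicates 1 and 2 of the protein, 29 and 44 of 58 still passed for ElavWT, 22 and 38 of 66 for FneWT and 38 and 37 of 64 for Rbp9WT. With the block and no filter 0 of 174 did. These results are of the named genes, chosen largely for the size of their change, so the rates do not describe all calls. Of all genes higher with the block, 81.5%, 78.6% and 58.4% still passed with median-ratio scaling in ElavWT, FneWT and Rbp9WT. Of all genes lower with the block, 100% did in each. The sign stayed the same in all of these settings with the block. Alternatives written beforehand for the distal ratio, the mutant proteins, the pooled test, uridine content and the distance between sites were not run. Depth limits genes near 0.639 CPM, which is 3 reads in the shallowest library.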

Other observations

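Some genes of stress and wound signalling were picked out after their values were seen, so their changes are no evidence for the group as a whole. The 26 heat shock and stress genes listed beforehand did not pass camera with any of the 3 proteins (adjusted p = 0.192, 0.145 and 0.295). Atf3, a transcription factor gene induced by stress, measured 307 ± 217, 370 ± 313 and 294 ± 197 CPM (SD, n = 2) in ElavWT, FneWT and Rbp9WT against 32.1 ± 10.1 CPM in untreated cells (adjusted p = 3.66e-07, 1.1e-07 and 4.14e-07 in the paired limma fit). Mmp1, a matrix metalloproteinase gene, measured 89.4 ± 100.2, 216 ± 221 and 86.7 ± 74.4 against 6.68 ± 5.09 CPM, and the cytokine gene upd3 77.8 ± 89.8, 87.3 ± 102.1 and 71.7 ± 66.8 against 7.72 ± 6.97 CPM. The glutathione transferase gene GstD4 reached 3.33 ± 0.117, 6.63 ± 3.46 and 19.7 ± 6.18 CPM from 0.143 ± 0.006 CPM. Ets21C, puc, rpr, Gadd45 and upd2 also rose with each protein, while Jra, kay, upd1 and GstD1 passed with none and cher fell in ElavWT.

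Of the explanations below, the tests of scaling, transfection, readthrough and spillover were chosen only after the results were seen. The 579 genes higher with all 3 proteins could reflect library scaling, low-level reads over silent genes, transfection itself or an activity that the proteins share. Under median-ratio scaling 75.8% of them (439) were still higher with each protein, so a common shift in scale does not account for most of these calls. Genes chosen for a large rise tend to outlast such a shift, and this scaling does not single out the rRNA share. With rRNA-named genes removed, 93.8%, 98.7% and 94.1% of all genes higher in ElavWT, FneWT and Rbp9WT still passed the paired fit. Their rise was 13 times (quartiles 4.2 and 36.7) what the per-kb level of silent genes predicts for their span, but genes chosen for a large rise are bound to exceed such an average, so background reads stay open. Transfection or overexpression of any protein was left open, since 0 mutant libraries were analysed and the labels do not describe a mock transfection. A shared activity of the proteins may therefore explain the rise no better than a response to transfection.

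Little-expressed genes that rose with all 3 proteins often lay just downstream of an expressed gene on the same strand, as 96 of 318 did (30.2% against 19.8% of 2050 others, 10.4 points, permutation p = 1.2e-04, adjusted p = 6.07e-04 over 28 tests). Reads from beyond the end of the upstream gene could explain this. An excess of 7.3 points on the other strand downstream (permutation p = 8e-04) was not predicted. Such neighbours end facing the gene, and whether counting used strand is not given, so this excess does not decide against the explanation. Other-strand genes upstream, which end facing away, differed by -5.1 points (permutation p = 0.0412, adjusted p = 0.0721 over 28 tests). The question stays open. Neighbouring genes that change together could also contribute, and the same-strand downstream excess was 4.1 points (SE 2.3, permutation p = 0.065), too imprecise to decide. Without untreated replicate 2 the same-strand upstream excess was 1.8 points, and without untreated replicate 1 it was 14.7 points. With median-ratio scaling it was 11.5 points (permutation p = 6e-05). No biological explanation was tested beyond these.

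fne rose in replicate 1 of ElavWT and Rbp9WT, which could reflect reads from the FneWT library of the same replicate. Its level in Rbp9WT replicate 1 was 117.9% of that in FneWT replicate 1, which spillover of a fraction of reads cannot give. Its rise in ElavWT replicate 1 was 47.5% of that in FneWT replicate 1, while Rbp9 reads reached ElavWT and FneWT replicate 1 at only 0.4% and 0.58% of the rise in Rbp9WT. Cross-regulation of fne by the other proteins was not tested. In the replicate 2 libraries, at 4.47 and 2.79 CPM against 1.91 CPM in untreated replicate 2, the rise was smaller. It rested there on 21 and 14 reads against 13 (unshifted log2 change 0.912 and 0.381).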
